A study of Homo sapiens with 6 samples.

How the data were processed

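RNA sequencing was done on 6 samples of MDA-MB-231, an established human triple-negative breast cancer line, in which MLL3, the histone methyltransferase encoded by KMT2C, had been deleted. Per the labels' protocols, the cells were kept for 14 days in 10 µM forskolin, an activator of adenylyl cyclase that raises cAMP and so protein kinase A activity. They were then sorted on surface CD104, the integrin beta-4 protein, into a CD44-positive CD104high population (n = 3) and a CD44-positive population with little or no CD104, called CD104low below (n = 3). The labels number biological replicates 1 to 3 in each population and name no batch, day or culture, so p-values measure the spread between these samples. The series design also speaks of wild-type cells, which were not analysed here.

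The submitters' processing notes name FastQC, Salmon 1.3.0 and DESeq2 with the build GRCh38 (hg38), without their order. The annotation release, the filters and the model formula are not given in the sources used here. The deposited table holds 15024 genes with symbols, and no gene in it has a 0 in any library. Its row numbers reach 19895, so 4871 numbers are absent, and genes outside the table were not analysed here.

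Per the file headers, the authors deposited for each gene a scaled read signal per library, a log2 fold change of CD104high against CD104low with its standard error in log2 units, a p-value and an adjusted p-value. Whether libraries other than these 6 entered the authors' fit is not given in the sources used here. The authors' p-value is empty for 2 genes and their adjusted p-value for 292. Within a library every value of the deposited signal was a whole multiple of the same step, as counts divided by 1 size factor per library would be. Dividing by the step gave whole numbers within 0.01 for 100% of the values in each library. For replicates 1 and 2 of CD104low the step lay too close to 1 for an automatic check of steps to judge. The count tests, used only as alternatives, rest on the recovered numbers of all 6 libraries. If Salmon made them, these numbers are rounded estimates of reads and not reads counted one by one.

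The recovered reads over the listed genes summed to 57975198, 60069719 and 53878182 in CD104high and to 54969422, 52751808 and 49791498 in CD104low. These sums leave out genes outside the table and are not the full depth of the libraries. No pair of replicates held identical values, and replicates of a population differed well beyond sampling noise, with a chi-square per degree of freedom of 12.74 to 44.62.

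The main test was limma 3.58.1 with an intensity trend, in R 4.3.3, on log2(value + 1), with genes kept that had a value of at least 10 in at least 3 samples. Population was the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on the log2(value + 1) scale understates the change of genes with low values. Levels are given as the mean ± SD of the scaled read count. Gene lists were tested with camera, which compares the members of a list with all other genes, at its preset correlation of 0.01, over lists with at least 4 tested genes. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

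The test, the alternatives and 32 gene lists were fixed before the data were examined, with the rule for named genes. The rule took ITGB4, CD44 and KMT2C, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50, non-overlapping populations and a symbol that is not a clone name. It also took up to 4 members of each list, the 2 with the smallest p in each direction. It gave 126 genes. Members named to spell out a small count, and genes described in the text as chosen after their values were seen, fall outside it. Single values of a few genes that enter the counts are not reported here. A further 10 gene families were listed after the data had been examined and appear only in the closing section. The erythroid list had no gene in the table and was not analysed here. The lists of sort markers and of endothelial genes had 2 tested genes each and were not tested as lists.

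Gene positions, biotypes, transcript lengths and GC content came from GENCODE 29 on GRCh38, matched by gene identifier for 14994 genes, or 99.8% of the table. Length and GC content were those of the longest annotated transcript of a gene, which need not be the one expressed here. Reads of near-identical genes, such as the HLA, IFIT, GBP, AKR1C, histone and ANXA8 families, can be divided between copies, so values of single members are uncertain. Whether the counting used strand is not given in the sources used here, so a gene and its antisense partner may share reads.

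Alternatives were a fit with the replicate number as a block, other scalings, filters and pseudocounts, limma without the trend, leaving out each library in turn, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the authors' own p-values, stricter thresholds and the ratio of group means. Random lists without matching were planned only for a table with no values per sample and were not run. After the data were seen, a correction was added that removes from each library a smooth trend (a natural spline with 4 degrees of freedom each) in log2 transcript length and GC content. It was run in 2 forms, keeping or not keeping each library's mean. The form that keeps the mean was taken as the corrected value in the text after the counts from both had been seen. Random lists matched on expression (10 bins), transcript length (5 bins) and GC content (5 bins) were drawn 10000 times. Each gene was drawn independently from genes of the same bins, the list's own members included. The shares of random lists therefore do not allow for correlation between genes. They were computed with 1 added to the count and to the draws. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

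The main test was tested on counts simulated for the same 14420 genes and 6 libraries, with 200 genes changed. It called 58% of genes changed 1.5-fold (47 of 81), 75.9% of those changed 2-fold (44 of 58) and 96.7% of those changed 4-fold (59 of 61), and 13 of 14220 unchanged genes. Camera called the 1 simulated list with a planted change and 0 of 29 others. The simulated genes varied independently of each other, so this cannot show how correlation between genes affects the list calls. Far fewer genes were changed than were called in the data, so the shares called need not hold there.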

Results

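The data were scaled read counts of 15024 genes in 6 libraries of MLL3-null, forskolin-treated MDA-MB-231 cells, 3 from CD104high and 3 from CD104low cells. Between 49791498 and 60069719 reads per library fell on these genes. The study's design calls CD104high cells a hybrid epithelial and mesenchymal state and CD104low cells mesenchymal, and the comparison asks how their transcriptomes differ. All 6 samples were MLL3-null, so the effect of MLL3 loss itself was not analysed here.

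CD104high cells had higher levels of interferon-stimulated and antigen-presentation genes, of hemidesmosome and laminin-332 genes, and also of genes counted as mesenchymal, several of them collagens. CD104low cells had higher levels of MYC, of S phase genes and of heat shock genes. Camera called these lists at its preset correlation, and none with an estimated correlation, where the adjusted p was 0.472 to 0.516. NGFR, the low-affinity neurotrophin receptor, rose and was at 114 ± 84.3 (SD, n = 3) in CD104high and 9.42 ± 9.56 (SD, n = 3) in CD104low, 11.5-fold on the log2(value + 1) scale. Its log2 fold change of 3.53 was 4.32 without replicate 2 of CD104high, and 2.85 and 4.26 without replicates 2 and 3 of CD104low. IL11, an interleukin-6 family cytokine, was 3.08-fold lower in CD104high, at 3617 ± 483 (SD, n = 3) against 11195 ± 1973 (SD, n = 3).

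Of 14420 genes tested with limma, 6257 (43.4%) changed, 3140 being higher and 3117 lower in CD104high. Most of these differences were small, with a median absolute log2 fold change of 0.49. Requiring a log2 fold change of at least 1 in size left 842 genes, 705 higher and 137 lower. In 7833 genes (54.3%) the populations did not overlap, where chance gives 10% for 3 against 3. The authors' deposited table called 6738 genes, and 6064 of the 6257 were among them in the same direction. Without replicate 1 of CD104low the count was 4097.

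ITGB4 (ENSG00000132470.14; GRCh38 chromosome 17, 75721328 to 75757818), which encodes the protein the cells were sorted on, was at 16463 ± 2616 in CD104high and 1699 ± 503 in CD104low (SD, n = 3 each). Its log2 fold change of 3.30 (SE 0.19, limma adjusted p = 0.000126) follows from the sort and checks the labels. CD44 (chromosome 11, 35138870 to 35232402), present on both populations by the sort, was at 25592 ± 3169 and 24651 ± 1232 (log2 fold change 0.05, SE 0.09, limma adjusted p = 0.708). KMT2C (ENSG00000055609.18; chromosome 7, 152134922 to 152436005), the deleted gene, still gave reads in every library, with 3934, 3561 and 3952 in CD104high and 2095, 2611 and 2814 in CD104low. A value for the whole gene does not show which exons were read, and no wild-type library stands beside it, so it does not check the deletion. The KMT2C difference of 0.62 (SE 0.11, limma adjusted p = 0.0027) became 0.31 with the correction for transcript length and GC content, and 0.23 (adjusted p = 0.103) where the correction did not keep library means.

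**Figure D1:**
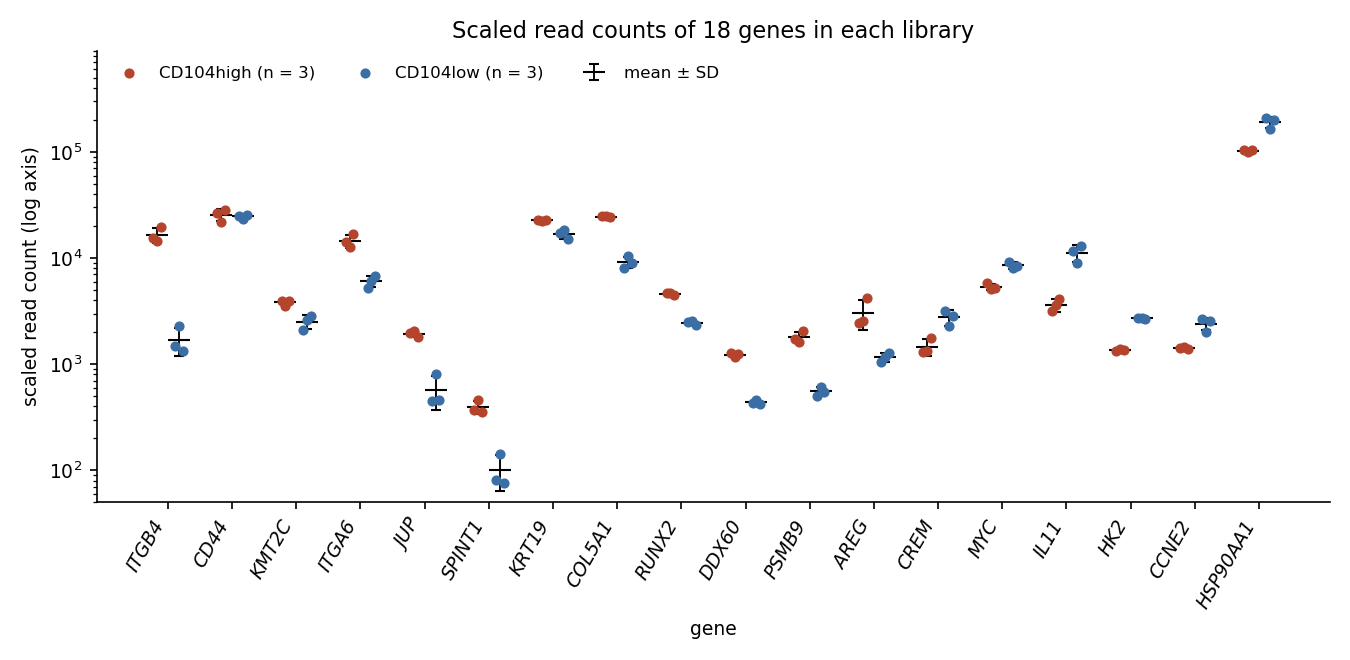
Scaled read counts (log axis) of 18 genes, with 1 point per library, in CD104high (red, n = 3) and CD104low (blue, n = 3); black bars are the mean ± SD. ITGB4 lies at 16463 ± 2616 against 1699 ± 503, CD44 overlaps between the populations, and MYC, IL11, HK2 and HSP90AA1 lie lower in CD104high.

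Beside NGFR and ITGB4, the largest rises with all 6 libraries were in PLEKHS1 (log2 fold change 3.05), LDOC1 (2.93), the cell adhesion molecule L1CAM (2.58), the neutrophil collagenase MMP8 (2.52), ANXA8L1 (2.48), GGT5 (2.34), EHD3 (2.32) and the placental alkaline phosphatase ALPP (2.32). ANXA8L1 has a near-identical copy, ANXA8, and its own share of the reads is uncertain. The limma adjusted p of these genes lay between 0.000126 (ITGB4) and 0.017 (MMP8), and MMP8 was at 0.0523 in limma without the trend. The log2 fold change of MMP8 was 1.72 and 3.14 without replicates 1 and 3 of CD104low, and that of LDOC1 was 2.23 without replicate 2 of CD104low. L1CAM was at 4083 ± 2455 in CD104high and 632 ± 300 in CD104low (SD, n = 3 each).

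The largest falls were in PEAR1 (log2 fold change -2.22), FAM24B (-2.18), the cardiolipin synthase CRLS1 (-1.91), the RNA polymerase III subunit POLR3G (-1.79), FGF5 (-1.78), TBC1D30 (-1.71), the sulfiredoxin SRXN1 (-1.69), IL11 (-1.62), the U3 small nucleolar RNA gene SNORD3B-2 (-1.62) and SNCAIP (-1.57). SRXN1 and CRLS1 varied widely within CD104high, where SRXN1 read 98.9, 171.2 and 552.6 and CRLS1 178.5, 290.4 and 911.5. Without replicate 3 of CD104high their log2 fold changes were -2.38 and -2.58. CRLS1 had an adjusted p of 0.055 without replicate 1 of CD104low. SRXN1 had 0.0698 without replicate 1 of CD104high, 0.0702 without replicate 2, and 0.0768 and 0.0623 without replicates 1 and 3 of CD104low. It had 0.0746 in limma without the trend and 0.0567 to 0.115 in the count tests. In the authors' deposited table, SRXN1 (adjusted p = 0.0789) and TBC1D30 (0.0785) did not pass.

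Hemidesmosomes anchor epithelial cells to laminin-332 through the integrin of ITGA6 and ITGB4. Of 11 genes in this list 7 rose and 0 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.55. ITGA6 rose 2.4-fold, from 6038 ± 740 to 14492 ± 2056 (SD, n = 3 each), and LAMA3 by 0.76 on the log2 scale. COL17A1, ITGB1, CD151 and LAMB3 did not pass, at 0.51, 0.13, 0.11 and 0.10. Camera called the list (adjusted p = 0.000266), with adjusted p = 0.472 with an estimated correlation. A test without ITGB4, chosen after the data were seen, gave adjusted p = 0.00147. The median of the full list, with ITGB4, was 0.29 with the length and GC correction.

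Keratins are the intermediate filaments of epithelial cells. Of 7 keratin genes 5 rose and 0 fell, the same adjusted over the list alone: KRT80 (0.48), KRT19 (0.45), KRT81 (0.41), KRT18 (0.34) and KRT7 (0.33). KRT8 was at 0.20 and KRT15 at -0.34, and neither passed. KRT5, KRT6A, KRT6B, KRT14, KRT16 and KRT17 were also listed but were not analysed here. The list was called by camera (adjusted p = 0.0422, and adjusted p = 0.516 with an estimated correlation). Its call ended without replicate 3 of CD104high (0.0636) or replicate 2 of CD104low (0.0798), in edgeR (0.0523) and with the length and GC correction (0.0851). The list median was 0.34, and 0.31 with that correction. KRT18 alone had an adjusted p of 0.0527 without replicate 1 of CD104low, and KRT80 was 0.31 with the correction and 0.23 (adjusted p = 0.0776) where it did not keep library means.

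Among 25 genes of epithelial junctions and epithelial identity, 10 rose and 1 fell, and 10 and 3 did so adjusted over the list alone. SPINT1, an inhibitor of the hepatocyte growth factor activator, rose 4.06-fold, from 101 ± 37.4 to 397 ± 57.2 (SD, n = 3 each), and JUP, the junction protein plakoglobin, 3.53-fold, from 570 ± 202 to 1937 ± 119 (SD, n = 3 each). AP1M2, a clathrin adaptor subunit of epithelial cells, fell by 0.47 on the log2 scale. CLDN3 was at -0.48 (limma adjusted p = 0.0507), and at 0.0234 and 0.0468 without replicate 3 of CD104high or of CD104low, 0.0435 with the length and GC correction and 0.0107 in the authors' deposited table. EPCAM, named after its value was seen, lay at -0.32 (adjusted p = 0.0531). The list was not called (camera adjusted p = 0.0869), except without replicate 1 of CD104low (0.0356) and in fry (0.026). CDH1 and GRHL2 were not analysed here.

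Basal breast and myoepithelial genes gave 4 rises and 0 falls among 9, or 5 and 0 adjusted over the list alone. NGFR, the myosin kinase MYLK (1.42), TRIM29 (1.01) and EGFR (0.30) rose, while TP63 (1.80, SE 0.73, limma adjusted p = 0.0752), OXTR (1.00), ACTA2 (0.67), CAV1 (0.35) and SFN (-0.05) did not pass over all genes. TRIM29 did not pass in the authors' deposited table (adjusted p = 0.117). The basal keratins KRT5, KRT14 and KRT17 of this list were not analysed here. The list was called by camera (adjusted p = 0.0253, and adjusted p = 0.522 with an estimated correlation). The call ended without replicate 3 of CD104high (0.0636), without replicate 2 of CD104low (0.0798), with no filter (0.0572) or a stricter filter (0.0824) on low values, and in fry (0.0644). Of 8 luminal genes 3 rose and 0 fell, or 2 and 0 adjusted over the list alone: ERBB3 (0.92), GATA3 (0.45) and KRT18. The luminal list was not called (camera adjusted p = 0.213).

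Genes listed as mesenchymal were also higher in CD104high, with 16 of 25 rising and 2 falling, the same adjusted over the list alone, and a median of 0.70. COL5A1, a chain of the fibrillar collagen V, rose 2.71-fold, from 9150 ± 1147 to 24638 ± 285 (SD, n = 3 each), and COL6A1, a chain of collagen VI, 2.01-fold. Fibronectin (FN1, 1.52) and the matrix protein TGFBI (1.57), both chosen after their values were seen, rose as well. COL3A1 fell by 1.20 and TAGLN by 0.44. The fall of TAGLN missed the threshold without replicate 1 of CD104high (0.0562) or replicate 1 of CD104low (0.0634). Vimentin (VIM), the intermediate filament of mesenchymal cells, was at 21251 ± 1831 and 20323 ± 386 (SD, n = 3 each; limma adjusted p = 0.517). Camera called the list (adjusted p = 0.000266), with adjusted p = 0.472 with an estimated correlation.

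Of 11 transcription factors of the epithelial to mesenchymal transition, 3 rose (FOXQ1, 2.05; RUNX2, 0.91; SOX9, 0.56) and 1 fell (TCF3, -0.28), the same adjusted over the list alone. With the length and GC correction TCF3 was at -0.51. FOXC1 was at -0.43 (limma adjusted p = 0.0751), and passed with the correction (-0.60, adjusted p = 0.0316), without replicate 3 of CD104high (-0.65, 0.00282), in DESeq2 (0.0459) and in the authors' deposited table (0.0269). SNAI1 (0.30), SNAI2 (0.22), ZEB1 (0.15) and ZEB2 (-0.04), named after their values were seen, did not pass. The list was not called by camera (adjusted p = 0.152), and fry gave 0.00245.

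Type I interferon-stimulated genes had the smallest camera p of the lists fixed beforehand. Of 31 genes 25 rose and 1 fell, or 26 and 1 adjusted over the list alone, with a median log2 fold change of 1.01. DDX60, a helicase of antiviral defence, rose 2.8-fold, from 437 ± 20.6 to 1227 ± 58.7, and the ubiquitin ligase gene HERC6 2.24-fold, from 444 ± 5.81 to 996 ± 37.2 (SD, n = 3 each). IFIT5 fell by 0.53, or by 0.30 with the length and GC correction. HERC5 (-0.01), USP18 (-0.04), IFI6 (0.23), IRF7 (0.44) and IFI44L (0.48) did not pass. Interferon gamma and antigen-presentation genes gave 23 rises and 0 falls among 33, the same adjusted over the list alone, with a median of 0.74. PSMB9, an immunoproteasome subunit, rose 3.24-fold, from 553 ± 56.3 to 1796 ± 214, and TAPBP, the peptide-loading protein tapasin, 2.2-fold, from 2717 ± 258 to 5975 ± 594 (SD, n = 3 each). SOCS3 (-0.22) and TAP2 (-0.23) did not pass, but did with the length and GC correction (adjusted p = 0.0355 and 0.0392), and TAP2 also with quantile normalization (0.0242). Camera called both lists (adjusted p = 1.58e-09 and 9.6e-07), and both had adjusted p = 0.472 with an estimated correlation. Single HLA, GBP and IFIT genes are uncertain because their reads can be shared. The leukocyte genes LAPTM5 (1.15) and CD14 (0.91) rose in the same libraries.

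**Figure D2:**
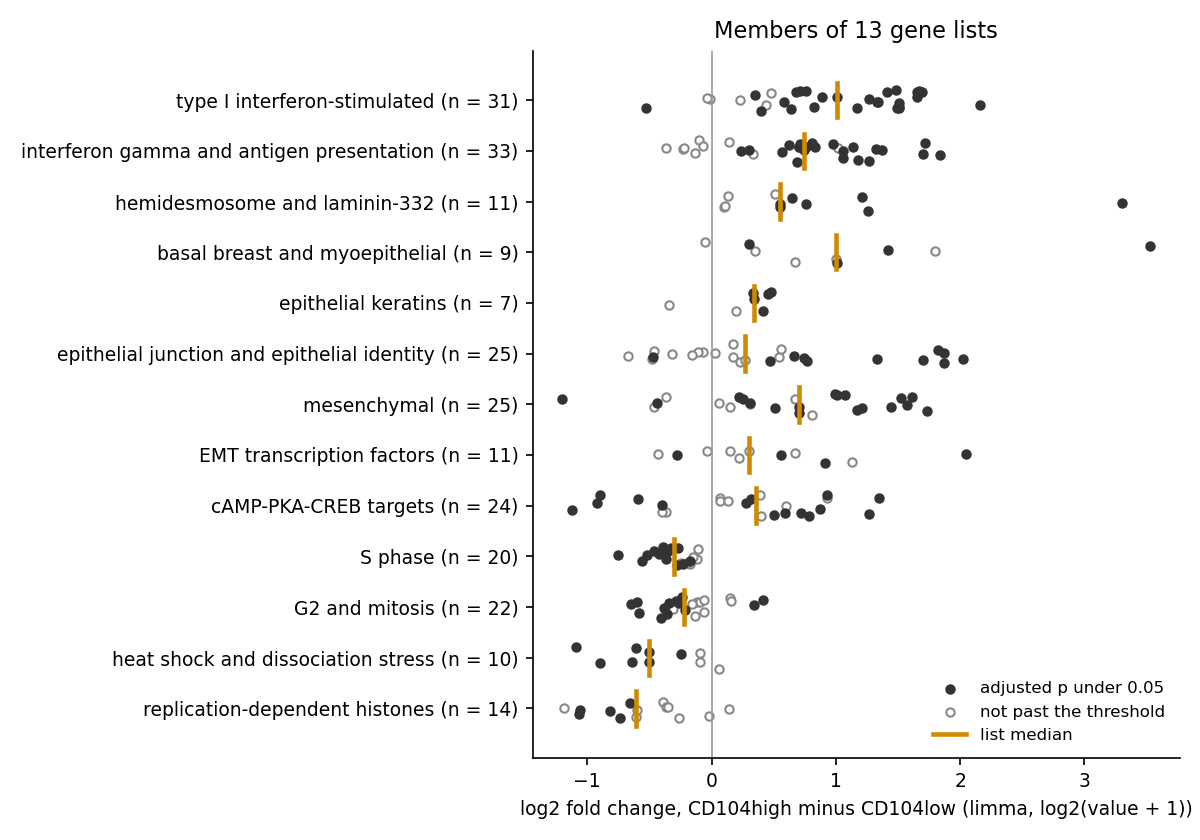
Log2 fold changes (CD104high minus CD104low) of the tested members of 13 gene lists, with 1 point per gene; filled points passed an adjusted p of 0.05 in limma, open points did not, and the bar is the list median. The medians run from 1.01 in type I interferon-stimulated genes to -0.61 in replication-dependent histones.

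Targets of cAMP, protein kinase A and CREB went both ways, with 10 rises and 5 falls among 24 genes, or 11 and 6 adjusted over the list alone. AREG, the EGF receptor ligand amphiregulin, rose 2.56-fold, from 1160 ± 103 to 3051 ± 969, and the phosphodiesterase PDE7B 1.72-fold, while CREM, which encodes a cAMP-response modulator, fell from 2765 ± 453 to 1463 ± 262 (SD, n = 3 each) and VGF fell by 0.90. AKAP12 (-0.40), PDE3B (-0.59) and CREB5 (-1.12) were the other falls, of which PDE3B did not pass in the authors' deposited table (adjusted p = 0.21). The list was not called by camera (adjusted p = 0.194), and fry gave 0.0486. All samples were treated with forskolin, so this is not a comparison with untreated cells. Immediate early genes gave 4 rises and 6 falls among 15, the same adjusted over the list alone, and were not called (camera adjusted p = 0.729). FOS rose 2.68-fold, while JUN fell by 0.57 and the phosphatase DUSP1 by 1.17. The other rises were EGR1 (0.83), DUSP6 (0.36) and FOSL2 (0.41), of which FOSL2 was at 0.14 (adjusted p = 0.21) with the length and GC correction.

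MYC was lower in CD104high, at 5373 ± 359 against 8543 ± 584 (SD, n = 3 each; log2 fold change -0.67, SE 0.07, limma adjusted p = 0.000449). It belonged to 15 stem and progenitor genes of which 0 rose and 4 fell, the same adjusted over the list alone. The other falls were BMI1 (-0.70), PROCR (-0.48) and ID1 (-0.43), and the list was not called (camera adjusted p = 0.183), except in fry (0.011). NOTCH3 was at 0.72 (limma adjusted p = 0.106), and passed without replicate 3 of CD104high (0.046) or replicate 2 of CD104low (0.0103). Of 20 S phase genes 0 rose and 14 fell, the same adjusted over the list alone, with a median of -0.30. The replication factor GINS2 fell by 0.52, and CCNE2, which encodes cyclin E2, by 0.75, or by 0.46 with the length and GC correction. Camera called the S phase list (adjusted p = 3.25e-05), with adjusted p = 0.516 with an estimated correlation. In the list of G2 and mitosis, 11 of 22 genes fell and 2 rose, or 12 and 2 adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, fell by 0.65, while TOP2A (0.34) and CENPF (0.41, or 0.22 where the correction did not keep library means) rose. MKI67, chosen after its value was seen, was at 0.15 (limma adjusted p = 0.263). This list was called (camera adjusted p = 0.00861, and adjusted p = 0.522 with an estimated correlation), but not with the length and GC correction (0.0851). CDKN1A, the cell cycle inhibitor p21, rose 2.38-fold, from 2100 ± 175 to 5013 ± 676 (SD, n = 3 each).

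Heat shock genes gave 7 falls and 0 rises among 10, the same adjusted over the list alone, with a median of -0.50. The chaperone gene HSP90AA1 fell 1.87-fold, from 192434 ± 22832 to 102447 ± 2052 (SD, n = 3 each), and the mitochondrial chaperonin HSPD1 fell by 0.64. HSPB1 (0.06), DNAJB1 (-0.09) and BAG3 (-0.09) did not pass. Camera called the list (adjusted p = 0.000493), with adjusted p = 0.516 with an estimated correlation. Of 14 replication-dependent histone genes, 5 fell and 0 rose (4 and 0 adjusted over the list alone): H1-4, H4C3, H3C3, H1-2 and H2BC11. That list (camera adjusted p = 0.0259, and adjusted p = 0.516 with an estimated correlation) lost its call without replicate 2 of CD104high (0.0647), with a stricter filter (0.103), in edgeR (0.0523) and with the length and GC correction (0.216).

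Of the other lists none was called. TGF-beta and YAP targets gave 9 rises and 3 falls among 20, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.061), with the transglutaminase TGM2 2.09-fold higher and LTBP2 2.44-fold higher (1.29 on the log2 scale, and 0.84 where the correction did not keep library means), and CCN1 and CCN2 lower by log2 fold changes of -0.39 and -0.65. Alternatives that called this list included the fits without replicate 1 of CD104high (0.0256), without replicate 1 (0.0399) or 3 (0.0293) of CD104low, with quantile normalization (0.0263), in edgeR (0.0263) and in fry (0.0224). Matrix protease and inhibitor genes gave 5 rises and 1 fall among 11 (adjusted p = 0.173), the same adjusted over the list alone. ADAM8 (1.34), TIMP3 (1.18), TIMP2 (0.73), TIMP1 (0.38) and CTSB (0.28) rose, and SERPINE2 fell by 0.68, with an adjusted p of 0.551 in the authors' deposited table, where its SE was 0.81 against 0.16 in DESeq2 on the recovered reads. NF-kB and cytokine genes gave 4 rises (IL6, TNFAIP2, NFKB2 and RELB) and 4 falls (IL11, IL24, CXCL8 and NFKB1) among 20, or 5 and 4 adjusted over the list alone (adjusted p = 0.805). CXCL8 was at 110 ± 20.3 against 219 ± 9.37 (SD, n = 3 each), and at -0.44 (adjusted p = 0.0681) with the length and GC correction, which left TNFAIP2 at 0.37 and ended the call of NFKB2 (0.0634).

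Hypoxia and glycolysis genes gave 2 rises (NDRG1 and ALDOA) and 2 falls among 17, or 1 and 2 adjusted over the list alone (adjusted p = 0.69). The falls were in HK2, the hexokinase of the first step of glycolysis, at 1360 ± 30.5 against 2708 ± 15.2, and in the peptide hormone gene ADM, at 3261 ± 505 against 8141 ± 641 (SD, n = 3 each). That list had a median of 0.05 but a mean of -0.07 and a downward test. NDRG1 and ALDOA missed the threshold without replicate 1 of CD104low, at 0.065 and 0.0775, and ALDOA also without any other single library except replicate 2 of CD104high, at 0.0556 to 0.116. NDRG1 was also at 0.0511 in limma without the trend and 0.057 with the length and GC correction. Cholesterol synthesis genes gave 5 rises (LSS, SREBF2, STARD4 and MSMO1 among them) and 2 falls (SC5D and IDI1) among 20, or 2 and 2 adjusted over the list alone (adjusted p = 0.69). With the length and GC correction LSS went from 0.70 to 0.46, SC5D from -0.49 to -0.18 and IDI1 from -0.35 to -0.20 (adjusted p = 0.112). IDI1 also missed the threshold without replicate 1 or 2 of CD104high or replicate 1 or 3 of CD104low, at 0.0638 to 0.0855. Unfolded protein response genes gave 2 rises (DDIT4 and HERPUD1) and 4 falls (DDIT3, SDF2L1, PPP1R15A and ATF4) among 17, the same adjusted over the list alone (adjusted p = 0.152). DDIT4 and HERPUD1 both missed it without replicate 2 of CD104high (0.103 and 0.061) and without replicates 1 (0.136 and 0.0659) and 3 (0.0975 and 0.0504) of CD104low, and DDIT4 also in limma without the trend (0.0928) and in the authors' deposited table (0.0719).

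NRF2 target genes gave 2 rises (AKR1C2 among them) and 4 falls (SRXN1, GCLM, SLC7A11 and NQO1) among 13, the same adjusted over the list alone (adjusted p = 0.942). SLC7A11 missed the threshold without replicate 1 of CD104low (0.0571). Among 14 p53 targets, CDKN1A, TP53INP1 (1.03), GDF15, BBC3 and ZMAT3 rose and GADD45A fell, which is 5 and 1, or 5 and 2 adjusted over the list alone (adjusted p = 0.398, and 0.0486 in fry). GADD45A missed the threshold without replicate 1 (0.0614) or 2 (0.0673) of CD104high and replicate 1 (0.081) or 3 (0.053) of CD104low, and with the length and GC correction (0.0553). BAX was at -0.19 (limma adjusted p = 0.0529), and passed without replicate 2 of CD104low (0.0202), in edgeR (0.049), in DESeq2 (0.0346) and in the authors' deposited table (0.0209), among others. Of 17 genes of KMT2 complexes and enhancer regulators, 5 rose (KMT2C, EP300, CREBBP, KMT2D and KDM6A) and 2 fell (WDR5, -0.39; EZH2, -0.42), the same adjusted over the list alone (adjusted p = 0.437). EP300 went from 0.64 to 0.31 with the length and GC correction. Of 10 drug efflux and metabolism genes, CYP1B1 and ABCC3 rose and ABCC4 fell, the same adjusted over the list alone (adjusted p = 0.805). ABCC3, a multidrug resistance transporter, rose 3.52-fold, from 4197 ± 1366 to 14391 ± 2273, and CYP1B1 was at 9736 ± 7817 against 1625 ± 204 (SD, n = 3 each). The log2 fold change of CYP1B1 was 2.24, and 2.88 and 1.60 without replicates 2 and 3 of CD104high. ABCC4 missed the threshold without replicate 1 (0.0894) or 2 (0.0809) of CD104high and replicate 1 (0.0659) or 3 (0.0635) of CD104low.

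Markers of other cell types were looked for in the same libraries. Of 6 fibroblast genes 4 rose (COL1A2, LUM, COL6A3 and PDGFRB) and COL3A1 fell, the same adjusted over the list alone, and all 6 also stand in the mesenchymal list (camera adjusted p = 0.152, and 0.0423 without replicate 3 of CD104low). Of 5 leukocyte genes LAPTM5 (1.15) and CD14 (0.91) rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.239, and 0.00295 in fry). The endothelial genes KDR (0.26) and ESAM (-0.46) did not pass. ESAM passed under some alternatives, among them without replicate 2 of CD104high (0.0456), without replicate 3 of CD104low (0.0403) and in DESeq2 (0.0376). Of the 13 mitochondrially encoded genes, ND2 fell by 0.34 and the rest did not pass, the same adjusted over the list alone (camera adjusted p = 0.904, with a median of 0.01 and a downward test). With the length and GC correction that list was upward, with a median of 0.37, and called (adjusted p = 0.00983), COX2 went from 0.19 (adjusted p = 0.0859) to 0.49 (0.00281) and ND6 from 0.23 (0.216) to 0.63 (0.0179), and ND2 was at -0.01 (0.951). Leaving out 1 library put ND2 at an adjusted p of 0.0552 without replicate 1 of CD104low, COX2 at 0.0446 without replicate 2 of CD104high, ND6 at 0.0392 without replicate 3 of CD104high and ND1 (-0.24, adjusted p = 0.0656) at 0.0413 without replicate 3 of CD104low. COX2 also passed in the authors' deposited table (0.0385), and ND1 with quantile normalization (0.0352) and in DESeq2 (0.0339).

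Fold changes followed transcript length and GC content across the table. Over 12499 genes with a mean of at least 50, the log2 fold change rose by 0.133 per doubling of transcript length, with Spearman correlations across genes, which are not independent replicates, of 0.27 with length and 0.19 with GC content. The median log2 fold change was -0.26 in 983 genes with transcripts of at most 1466 bases and 0.22 in 1336 genes with transcripts of at least 7457 bases. Per library the slope was 0.082, 0.095 and 0.022 in CD104high and -0.106, -0.018 and -0.074 in CD104low. With the correction 5843 genes were called, 4694 of them among the 6257 in the same direction, and the medians of the type I interferon, interferon gamma, mesenchymal, S phase, G2 and mitosis, heat shock and histone lists were 1.04, 0.67, 0.79, -0.34, -0.16, -0.35 and -0.35.

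**Figure D3:**
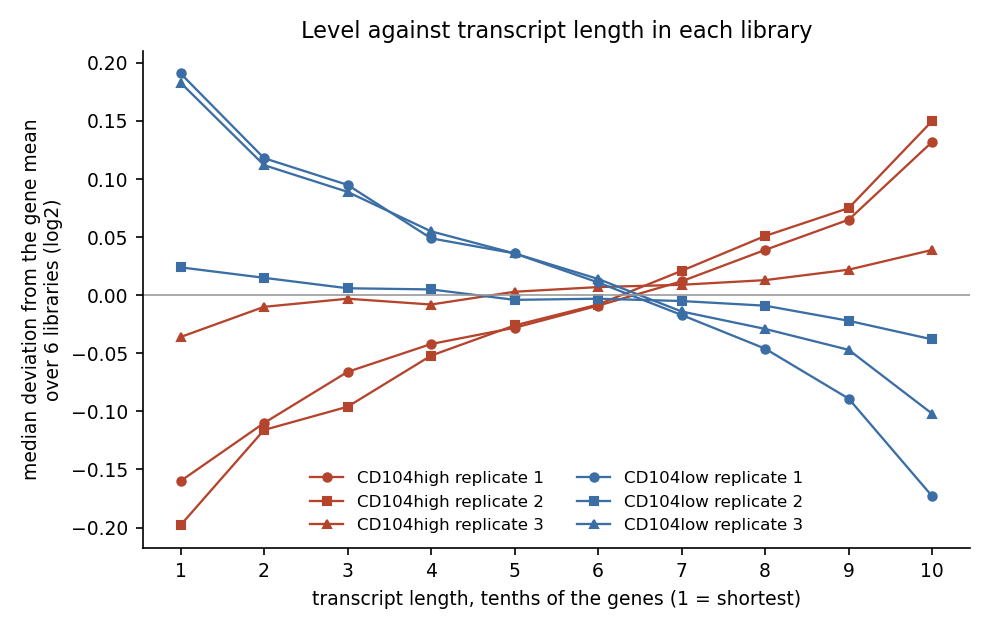
Median deviation of genes from their mean over the 6 libraries (log2), in 10 bins of transcript length, with 1 line per library in CD104high (red) and CD104low (blue). In the bin of longest transcripts the libraries lie at 0.13, 0.15 and 0.04 in CD104high and at -0.17, -0.04 and -0.10 in CD104low, with replicate 3 of CD104high and replicate 2 of CD104low nearest 0.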

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

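The length and GC corrections and the hemidesmosome and integrin lists without ITGB4 were chosen after the data were seen. Against 6257 changed genes (3140 higher, 3117 lower), leaving out 1 library gave 4097 to 6390 (2088 to 3192 higher, 2009 to 3198 lower), with 4097 without replicate 1 of CD104low, where fewer samples were fitted. An adjusted p of 0.01 gave 3642 (1803 and 1839) and a log2 fold change of at least 1 gave 842 (705 and 137). Stricter thresholds lower the totals by construction. They do not set the split, which was 83.7% higher at the fold threshold against 50.2% in the main test. The length and GC correction gave 5843 (2837 and 3006); without keeping library means it gave 6145 (2194 higher, 3951 lower), so 35.7% of calls were higher against 50.2%, since the median of all genes moved from 0.019 to -0.064. Other scalings, filters, pseudocounts, edgeR (6244), DESeq2 (6625) and the authors' p-values stayed within 1.5 times. With the replicate block the count was 7876, and the TGF-beta and YAP list (adjusted p = 0.0448), the fibroblast list (0.0431) and ESAM (0.000328) were among the results that gained a call. Same-numbered libraries correlated at 0.084, 0.359 and 0.324 in their deviations from the population means, not all above 0.1, so the labels' numbers were not taken to pair samples; every library correlated best with its own number, which is a hint from the data and not from the design. The 10 lists called by camera became 0 with an estimated correlation, 0 with the length and GC correction and an estimated correlation, and 16 in fry, which tests another question; at an unadjusted p 2 of 29 lists passed in each of the first 2, with an estimated correlation alone the hemidesmosome (0.0293) and type I interferon (0.0446) lists. The mitochondrially encoded list, not called and downward, was upward and called with the length and GC correction (adjusted p = 0.00983, or 0.011 without keeping library means), against 0.00983 to 0.994 over its 20 alternatives. Its uncorrected median was 0.01, against -0.35 in random lists matched on expression, length and GC content. The upward call thus came from removing a trend that these genes did not follow. Why they did not follow it was not tested. Of 29 lists, the 10 that were called each lost the call under at least 1 alternative, 8 uncalled ones gained a call in their own direction, the mitochondrially encoded list gained one in the other, and 10 uncalled ones gained none, while the direction of uncalled lists flipped 20 times over all lists and alternatives. Of 126 named genes 103 passed the threshold, 88 stayed on their side of it under all alternatives run, 24 lost a call under at least 1, 14 gained one and 0 changed direction with a call. Depth limits genes with low values and reads outside the table; at 3 against 3 the test called 58% of simulated 1.5-fold changes.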

Other observations

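The tests of chance splits, of the length and GC trend, of single libraries and of library preparation were chosen after the results they bear on had been seen, as were the gene families described first and the integrin test without ITGB4.

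Genes for making proteins, listed proteasome subunits, and nucleus-encoded genes of the mitochondrial ribosome, protein import and complex I, were lower in CD104high. Of 60 ribosome biogenesis genes 54 fell and 1, NOP9, rose, with a median log2 fold change of -0.59, for example in the rRNA methyltransferase FBL (-0.61) and the processing factor BOP1 (-0.91). Of 83 cytosolic ribosomal protein genes 67 fell and 0 rose (median -0.41), of 76 mitochondrial ribosomal protein genes 59 fell and 0 rose (-0.49), of 34 proteasome subunits 30 fell and 0 rose (-0.41), of 25 mitochondrial import genes 19 fell and 0 rose (-0.44), of 45 complex I genes 22 fell and 0 rose (-0.35), and of 17 tRNA synthetases 10 fell and 1, QARS1, rose (-0.25). The proteasome family as listed leaves out the immunoproteasome subunit PSMB9, which rose (log2 fold change 1.70). Camera called each family, from adjusted p = 2.38e-19 for ribosome biogenesis to 0.000235 for the tRNA synthetases. Here and below, p-values of families were adjusted only over the 10 families listed after the data had been examined. With an estimated correlation the adjusted p was 0.158 to 0.216. With the length and GC correction the medians were -0.52, -0.35, -0.35, -0.27, -0.33, -0.18 and -0.21, in the order given.

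Collagens and integrins were higher. Of 28 collagen genes 14 rose and COL3A1 fell (median 0.81), including the basement membrane chains COL4A3 (2.07) and COL4A4 (1.84). Of 17 integrin genes 10 rose and ITGAE fell (median 0.78), a count that includes the sorted ITGB4 beside ITGB8 (1.38) and ITGB3 (1.06). Camera gave adjusted p = 9.6e-06 and 7.69e-05, and both families had adjusted p = 0.158 with an estimated correlation. Without ITGB4, 9 of 16 integrin genes rose and 1 fell (median 0.72), with a camera adjusted p of 0.000326, adjusted p = 0.162 with an estimated correlation and 0.00117 with the length and GC correction. With that correction the medians of the full families were 0.52 and 0.62, and random lists matched on length, GC content and expression had medians of 0.33 and 0.14.

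The count of changed genes was set against the 10 ways of splitting the 6 libraries into 3 and 3. Only 1 split, the real one, gave as many calls (6257), and the highest other gave 0 in limma. The other splits mixed CD104high and CD104low within a group, so the difference between the populations entered their spread and held down their calls. With 10 splits the share also cannot fall under 0.05, so the splits do not decide about chance.

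Interferon and antigen-presentation genes were higher in CD104high in 25 of 31 and 23 of 33 genes, with a median of 0.79 over the 64 genes of both lists. The trend with transcript length and GC content is argued against, since none of 10000 matched random lists had a median as high. The share of 0.0001 is the smallest that 10000 draws can give, and the matched median was 0.0. Genes were drawn independently, so the share does not allow for correlation between genes. A single library is argued against too, since the highest adjusted p of either list without each library in turn was 4e-06, with 2.3e-10 the lowest. Shared reads within families do not account for all of it. Without the HLA, GBP, IFIT, OAS, MX, SAMD9, HERC, PSMB and IFI44 genes the higher camera adjusted p, adjusted over these 2 lists alone, was 0.0131. The medians were 0.28 over 16 genes of the gamma list, 8 of them called higher, and 0.91 over 16 of the type I list, 13 called higher. What stays open is that neither list is called with an estimated correlation (adjusted p = 0.472, against 2.07e-14 to 0.524 over the alternatives of the type I list and 2.1e-10 to 0.524 over those of the gamma list), and that a difference between the sorted populations in interferon signalling, a hypothesis that may explain the rise, was not tested.

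Longer and GC-richer transcripts were higher in CD104high. Low levels of the listed short biosynthesis genes are argued against as the main source. Without those families, histones and heat shock genes, 93.7% of the slope was left. That kept 12118 of 12499 genes, so short biosynthesis genes outside the lists were not tested. Library preparation or RNA integrity cannot be told apart from the populations, since the labels name no batch and the lowest slope in CD104high lay 0.04 above the highest in CD104low. Replicate 3 of CD104high and replicate 2 of CD104low, with slopes of 0.022 and -0.018, lay nearest 0. A real difference in the length of expressed genes stays open as well and was not tested.

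Growth and replication genes were lower in CD104high, and the trend with length and GC content stays open for G2 and mitosis (median -0.22 against a matched median of -0.15, with a share of 0.176 of matched random lists as low), which lost its call with the correction (adjusted p = 0.0851, against 0.0022 to 0.653 over its alternatives). Complex I (0.0263) and tRNA synthetases (0.0283) stood less far from matched lists but stayed called with the correction (adjusted p = 0.000188 and 0.000248), with medians going from -0.35 to -0.18 and from -0.25 to -0.21, which argues against the trend as their whole cause. Matched lists argue against the trend as the whole cause for S phase (0.0055), ribosome biogenesis (0.0001), cytosolic (0.0001) and mitochondrial (0.0001) ribosomal proteins, mitochondrial import (0.0014) and the proteasome (0.0008). Their matched medians were themselves negative, at -0.11, -0.08, -0.21, -0.24, -0.19 and -0.19 in that order. Genes were drawn independently, so these shares do not allow for correlation within the lists. For histones the share was 0.0021 over 12 matched genes. The shortest of the 5 length bins reached 2027 bases, against 642 and 754 for H1-2 and H1-4, so this matching was coarse. The same bins served the other lists. The histone list lost its call with the correction (adjusted p = 0.216, against 0.00818 to 0.538 over its alternatives). Its median went from -0.61 to -0.35, and the trend stays open there too. A candidate explanation is lower MYC-linked biosynthesis, since MYC itself fell, tested on 25 genes of nucleotide, polyamine and one-carbon synthesis and classical MYC targets outside the other lists. Of these 21 fell and 0 rose, which is consistent with that hypothesis, found and tested on the same data, but does not show that MYC acts on them, with a median of -0.35 against a matched median of -0.10, and a share of 0.0005 of matched lists was as low (camera adjusted p = 1.65e-08, and adjusted p = 0.158 with an estimated correlation).

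The authors' standard errors were at least 2 times those of DESeq2 on the recovered reads of these 6 libraries for 62 genes and at most 0.5 times for 0, with a median ratio of 0.932. An example chosen after its values were seen is the actin bundler FSCN1 (0.26 against 0.12).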
